A study of Mus musculus with 15 samples.

How the data were processed

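RNA was taken from hearts of male C57BL/6 mice with Trizol, depleted of rRNA and made into libraries with an NEB kit, per the labels' protocols. The 15 libraries fell into Control, AngII and AngII+QDG by their labels, 5 mice per group per the series' design text. The dose and duration of AngII and QDG, the aligner and the quantification tool are not given in the sources used here. The submitters' processing notes name the genome build GRCm38 and limma.

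The authors deposited 1 table per library, read here as FPKM per transcript. The unit was inferred from the values: the sum of value times transcript length was nearly the same in every library, as FPKM requires, and the headers do not state it. Control and AngII files listed 31685 transcripts and AngII+QDG files 31734, of which 29996 were in both. No library pair held identical values (0 pairs). Of 24789 Ensembl transcripts, 24756 were named with GENCODE M21 on GRCm38. Another 8634 were assembled transcripts without a gene name and were tested only as transcripts. Named transcripts were summed to 12380 genes with a transcript in both sets of files. A transcript listed in only 1 set adds to its gene there alone, so counts over shared transcripts were an alternative. Reads shared between paralogs, pseudogenes or nuclear copies of the mitochondrial genome could be split between them, and such genes are uncertain.

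Depth was read from the values. FPKM times length in kb fell on whole multiples of a step of each library: 97.0 to 97.2% of named transcripts above 0, and 99.2 to 99.8% of those of up to 10 steps, lay within 0.1 of a whole number, where chance gives 20%. Whether a step is a fragment or a read could not be told. Taken as 1 fragment, depth in units of 1000000 for replicates 1 to 5 was 65.7, 66.3, 67.6, 72.9 and 72.8 in Control, 56.6, 66.1, 62.4, 76.4 and 78.3 in AngII, and 52.4, 76.5, 61.8, 51.6 and 73.3 in AngII+QDG.

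Genes with at least 0.5 FPKM in at least 5 libraries (12258) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend and robust variance. All 15 libraries entered 1 fit with 12 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. Log2 fold changes are on this scale, which understates the change of low genes. Of 52 gene lists, the 46 with at least 4 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Library measures and list scores were compared by exact two-sided permutation tests over 252 arrangements. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

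The lists, 14 genes of interest, the model and most alternatives were set before the data were examined. Named genes were, per comparison, the 10 with the largest rise and the 10 with the largest fall among called genes with a mean of at least 1 FPKM in the higher group and no overlap between the libraries of the groups, predicted and clone-based models left out (where none was called, the 5 with the smallest p per direction). The 14 preset genes were named in every comparison, as were up to 4 members with the smallest p of each pathway list described and 3 of each cell type list. From the genes so chosen, 77, 36 and 54 in the order of the comparisons were followed across settings, and not all of them are named. Some genes that met this rule are not reported here. Other settings fixed then covered the pseudocount, the filter, quantile and median scaling, fits of 2 groups, the replicate number as a block, sample weights, a fold threshold and each library left out. Chosen after seeing the data were shared transcripts, transcripts instead of genes, mitochondrial genes left out, removal of each library's length trend, the short-against-long balance as a covariate, Control 3 and Control 5 left out, genes with a library at 0 left out, and limma voom on the recovered fragments.

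The steps were tested on simulated data. Among 12258 genes simulated on AngII and Control, 66% of 100 genes changed by 1 log2 unit and 93% of 100 changed by 2 were recovered, with 8 unchanged genes called. For AngII+QDG and AngII the shares were 69% and 92%, with 12 unchanged genes called. The simulated noise was independent between genes, had the same spread in every group and held no difference in short-against-long balance. Changes were placed in genes with a mean log2 value above 1. These shares therefore check the steps and do not measure the error in the real libraries.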

Results

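Hearts of male C57BL/6 mice were profiled by RNA sequencing of rRNA-depleted RNA. The 15 libraries formed 3 groups of 5 mice: Control, AngII (mice infused with AngII, angiotensin II, a peptide hormone that raises blood pressure), and AngII+QDG (AngII mice that also received QDG, a treatment the labels give only by this abbreviation). The stated aim was to find differentially expressed genes and related pathways. The values were FPKM per transcript, summed here to 12380 named genes, of which 12258 entered the tests. Low FPKM values rose in whole steps, and if 1 step is 1 fragment the libraries held 51.6 to 78.3 times 1000000 fragments. In the same unit, depth was 69.1 ± 3.54 in Control, 68.0 ± 9.26 in AngII and 63.1 ± 11.5 in AngII+QDG (SD, n = 5 each). No pair of groups was called different in depth (exact two-sided permutation test, smallest p = 0.294, adjusted p = 0.546 over 24 tests of library measures). Limma gene p-values and permutation p-values below measure the spread between these samples. Camera p-values compare list members with other genes at a preset correlation of 0.01. They do not take in how far members of a list vary together across libraries, which the estimated correlation does.

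Libraries differed in more than gene-by-gene values. Control libraries gave relatively more FPKM to short transcripts. The difference between 1600 protein-coding transcripts under 1000 nt and 4388 of at least 3000 nt was 1.64 ± 0.26 log2 units in Control, 1.17 ± 0.08 in AngII and 1.13 ± 0.12 in AngII+QDG (SD, n = 5 each). AngII minus Control was −0.47 (exact two-sided permutation p = 0.00794, adjusted p = 0.0635). Transcripts listed at 0 made up 11.4% ± 5.26 of Control, 4.80% ± 0.876 of AngII and 5.35% ± 0.756 of AngII+QDG (SD, n = 5 each; AngII against Control exact permutation p = 0.00794, adjusted p = 0.0635). Control 5 had 20% of transcripts at 0 at a depth of 72.8 times 1000000 fragments, and Control 3 and Control 5 had the strongest short-transcript balance, 1.90 and 1.91. Mitochondrial genes and their nuclear copies took 46.0% ± 6.45 of FPKM in Control and 42.3% ± 2.64 in AngII (SD, n = 5 each; exact permutation p = 0.278, adjusted p = 0.546). AngII and AngII+QDG libraries did not differ by any of these tests, where the smallest p was 0.286 (exact permutation, adjusted p = 0.546).

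**Figure D1:**
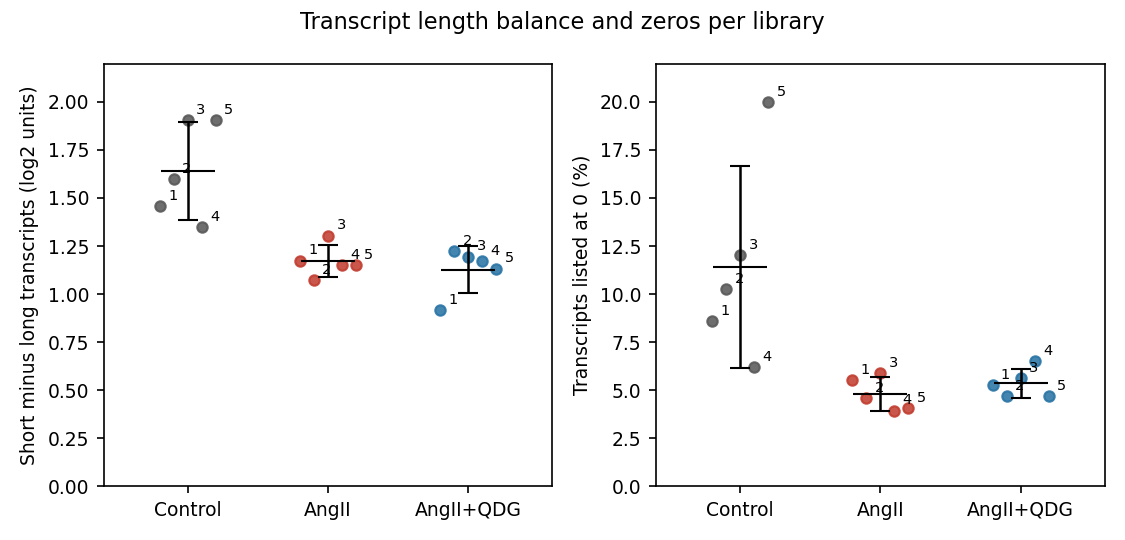
Balance of short against long transcripts (left axis, log2 units) and percent of transcripts listed at 0 (right axis) for each library, with replicate numbers beside the points and the group mean ± SD (n = 5) in black. The Control libraries lie between 1.35 and 1.91 log2 units on the left, above the AngII range of 1.07 to 1.3, and Control 5 reaches 20% on the right.

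The first comparison asked which transcripts differ in the heart after AngII infusion. Tnfrsf12a, Timp3 and Adamts1 were higher and Cox5b was lower in AngII than in Control hearts. Tnfrsf12a, the receptor of the cytokine TWEAK, rose from 53.1 ± 13 to 150.2 ± 39.2 FPKM (SD, n = 5 per group; log2 fold change 1.48 ± 0.19 SE, limma adjusted p = 0.00251). Timp3, an inhibitor of matrix metalloproteinases, rose from 24.5 ± 3.26 to 47.6 ± 5.05 FPKM (0.94 ± 0.15, adjusted p = 0.00711), and Adamts1, a secreted metalloproteinase, from 3.01 ± 0.913 to 10.1 ± 2.54 FPKM (1.48 ± 0.20, adjusted p = 0.00304). Cox5b, a subunit of cytochrome c oxidase, fell from 941 ± 119 to 665 ± 43.0 FPKM (−0.49 ± 0.09, adjusted p = 0.0101). For each of these 4 genes the highest library of the lower group lay below the lowest library of the higher group. In GRCm38, Tnfrsf12a (ENSMUSG00000023905) lies on chromosome 17 from 23675445 to 23677468, and Timp3 (ENSMUSG00000020044) on chromosome 10 from 86300372 to 86349506. Adamts1 (ENSMUSG00000022893) lies on chromosome 16 from 85793827 to 85803113, and Cox5b (ENSMUSG00000061518) on chromosome 1 from 36691449 to 36693681.

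Among the other genes called, some had larger log2 changes. Tjp1, a tight junction scaffold, rose by 2.16 ± 0.18 log2 units (SE; limma adjusted p = 5.84e-05), with 0.408 ± 0.316 FPKM in Control and 5.17 ± 0.545 in AngII (SD, n = 5 each). Lmo7, a junction-associated protein, rose by 2.46 ± 0.34 (adjusted p = 0.00376) and Sptb, the erythroid beta spectrin, by 2.27 ± 0.30 (adjusted p = 0.00304; 3.30 over transcripts listed in every file). Slmap, a sarcolemmal membrane-associated protein, rose by 3.21 ± 0.50 (adjusted p = 0.00688), and Flnc, the muscle filamin, by 1.32 ± 0.29 (adjusted p = 0.0189), or by 3.44 (0.0242) over transcripts listed in every file. Kcnj12, an inward rectifier potassium channel, rose by 1.49 ± 0.30 (adjusted p = 0.0138), and Bms1, a ribosome assembly factor, by 2.05 ± 0.21 (adjusted p = 0.000191). Tjp1 was listed at 0 in 1 Control library and Bms1 in 3. These 7 genes and the 4 of the paragraph above were the 11 still called without Control 3 and Control 5 among 59 called genes that were followed across settings, not all of which are named here. Btnl9, a butyrophilin-like protein, rose by 2.74 ± 0.44 (adjusted p = 0.00746) and Carns1, which makes carnosine, by 2.59 ± 0.53 (adjusted p = 0.0154), with Carns1 listed at 0 in 4 Control libraries; neither was called without Control 3 and Control 5.

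In all, limma called 1639 of 12258 genes between AngII and Control (1458 higher and 181 lower in AngII), and 3858 genes had an unadjusted p under 0.05. The median log2 change of all genes was 0.20, a shift that depends on scaling: quantile normalization called 406 higher and 412 lower, and median scaling 360 higher and 714 lower. The median itself was 0.11 without Control 5 and 0.077 without Control 3 and Control 5. Relative to that median the change was 1.28 for Tnfrsf12a, 0.74 for Timp3 and −0.69 for Cox5b. List medians below are given relative to it, gene values are not. The count was 97 (93 higher, 4 lower) without Control 3 and Control 5, and 0 in limma (749 at an unadjusted p under 0.05) with each library's short-transcript balance as a covariate, which also ended every named call. With that covariate the median size of the change of the 1639 genes went from 0.60 to 0.25 log2 units and the median standard error from 0.16 to 0.21. The change of 115 of them did not shrink. Tnfrsf12a went from 1.48 ± 0.19 to 1.66 ± 0.31, Ccn2 from 2.10 ± 0.35 to 2.13 ± 0.58, Timp3 from 0.94 ± 0.15 to 0.86 ± 0.24, Flnc from 1.32 ± 0.29 to 0.21 ± 0.30 and Cox5b from −0.49 ± 0.09 to −0.25 ± 0.11. Leaving out 1 library moved the count by over 1.5 times for AngII 2 (316), AngII 4 (474), AngII 5 (509), Control 3 (706), Control 5 (794), AngII 1 (878), Control 2 (982) and Control 4 (2488). A fit of these 2 groups alone called 317 genes and kept 24 of the 59 called genes followed across settings. With the replicate number as a block 40 of the 59 were kept.

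**Figure D2:**
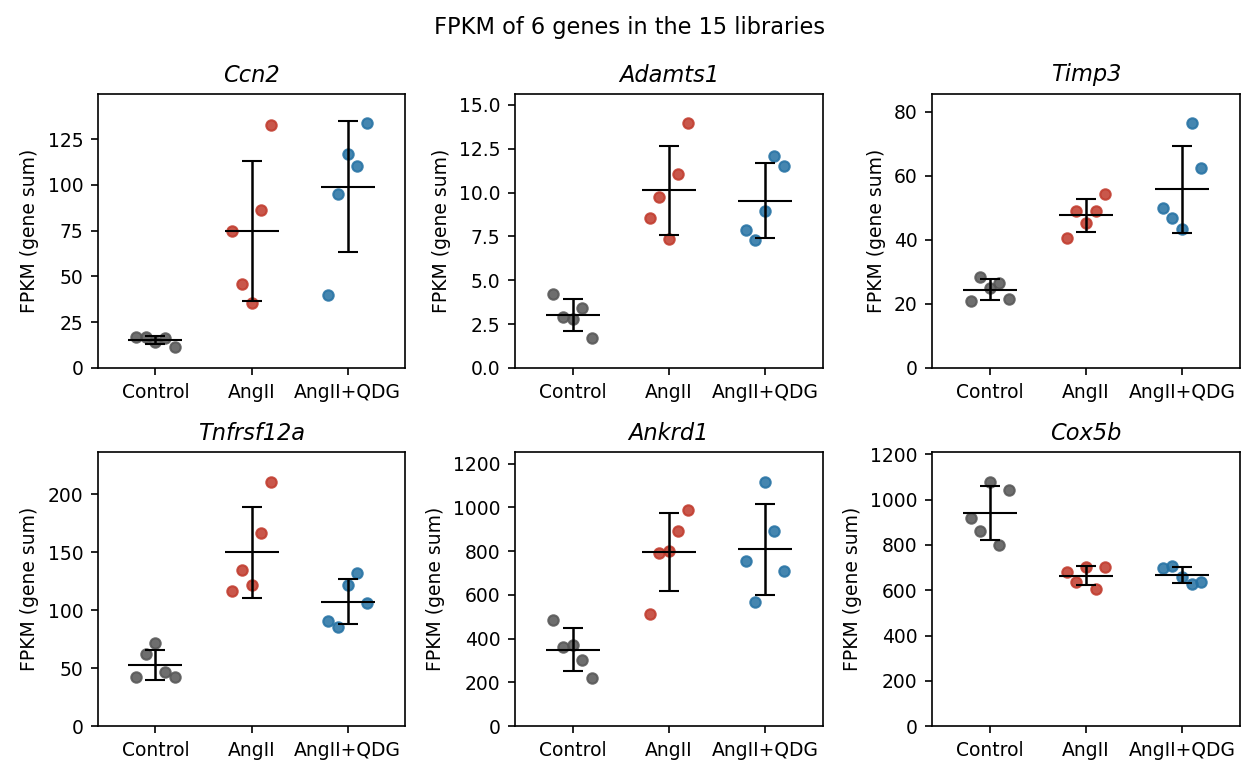
FPKM, summed per gene, of Ccn2, Adamts1, Timp3, Tnfrsf12a, Ankrd1 and Cox5b in the 15 libraries (vertical axes from 0), with group mean ± SD (n = 5) in black. In the AngII libraries the first 5 genes lie above every Control library and Cox5b below every Control library, at 604 to 703 against 800 to 1080 FPKM.

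Collagens and the enzymes that modify the matrix were higher as groups in AngII hearts. Of 16 collagens, 7 rose, 0 fell and 9 did not pass the test, with 7 higher when adjusted over the list alone (list median 0.51 log2 units above all genes, camera adjusted p = 0.0212; adjusted p = 0.783 with an estimated correlation). Col5a2 rose by 0.91 ± 0.21 (SE; limma adjusted p = 0.0199) and Col8a1 by 1.07 ± 0.24 (adjusted p = 0.0201), n = 5 per group. Of 23 matrix crosslinking and remodelling enzymes and their inhibitors, 6 rose, 0 fell and 17 did not pass, with 9 higher when adjusted over the list alone (median 0.27 above all genes, camera adjusted p = 0.00614; adjusted p = 0.783 with an estimated correlation). Without Control 3 and Control 5, 0 collagens (limma; camera adjusted p = 0.152) and 3 enzymes (camera adjusted p = 0.0208) were called, and the collagen list was not called without Control 3 (0.077) or AngII 5 (0.0576). Collagen transcripts were long, with a list median of 5456 nt for the longest transcript. With the length trend of each library removed both lists were called (camera adjusted p = 0.0395 for collagens and 0.00823 for enzymes), with 0 collagens and 3 enzymes called by limma. Of 12 fibroblast markers 2 rose and 10 did not pass (camera adjusted p = 0.271), and of 10 activated fibroblast markers 3 rose (4 adjusted over the list alone; camera adjusted p = 0.307). Among them Postn, the matricellular protein periostin, rose by 1.42 ± 0.39 (adjusted p = 0.032), a call that ended without Control 3 (0.073), Control 5 (0.0731), AngII 2 (0.0701), AngII 4 (0.0677) or AngII 5 (0.0761). Neither Col1a1 (0.67 ± 0.30, adjusted p = 0.136) nor Col3a1 (0.77 ± 0.79, adjusted p = 0.527) passed. With the short-transcript balance as a covariate Col5a2 went to 0.33 ± 0.27, Col8a1 to 0.62 ± 0.37 and Postn to 0.21 ± 0.49 (SE). Col1a1 then stood at −0.14 ± 0.41 and Col3a1 at −0.97 ± 1.19. Of the enzymes and inhibitors, Adamts1 went from 1.48 to 1.06 ± 0.29 and Timp3 from 0.94 to 0.86 ± 0.24.

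Of 14 natriuretic and fetal programme genes, 6 rose, 0 fell and 8 did not pass, with 8 higher when adjusted over the list alone (median 0.52 above all genes, camera adjusted p = 0.0415; adjusted p = 0.783 with an estimated correlation). Ccn2, the matricellular growth factor CTGF, rose by 2.10 ± 0.35 (SE; limma adjusted p = 0.0078), from 15.1 ± 2.18 to 75.0 ± 38.3 FPKM (SD, n = 5 each). Ankrd1, a stretch-responsive ankyrin repeat protein of cardiomyocytes, rose by 1.2 ± 0.22 (adjusted p = 0.0112), from 349 ± 97.2 to 797 ± 178 FPKM. Neither Ccn2 nor Ankrd1 was called without Control 3 and Control 5. Ccn2 (ENSMUSG00000019997) lies on chromosome 10 from 24595442 to 24598683 and Ankrd1 (ENSMUSG00000024803) on chromosome 19 from 36111961 to 36120099. Classical markers of the programme did not pass: Nppa, the atrial natriuretic peptide gene, changed by 0.69 ± 0.31 (adjusted p = 0.143), Nppb by 0.25 ± 0.73 (adjusted p = 0.846), Myh6 by −0.25 ± 0.28 (adjusted p = 0.564) and Myh7 by 1.03 ± 0.37 (adjusted p = 0.0763, and 0.0443 without Control 4). Acta1, skeletal alpha-actin, was called (1.33 ± 0.41, adjusted p = 0.0451), but not without any 1 of Control 1 (0.0521), Control 2 (0.0611), Control 3 (0.0878), Control 5 (0.101), AngII 1 (0.0641), AngII 2 (0.0537), AngII 4 (0.0958), AngII 5 (0.103), AngII+QDG 3 (0.0503) or AngII+QDG 4 (0.0553). The list's call ended without Control 3 (0.0729), Control 4 (0.0914), Control 5 (0.0657), AngII 4 (0.0758) or AngII 5 (0.0576), and its adjusted p was 0.0697 without Control 3 and Control 5.

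Immediate early genes, MAPK regulators and heat shock genes were also higher as groups. Of 21 immediate early genes 6 rose, 0 fell and 15 did not pass, with 9 higher when adjusted over the list alone (median 0.38 above all genes, camera adjusted p = 0.00583; adjusted p = 0.783 with an estimated correlation). Klf6, a zinc finger transcription factor, rose by 0.81 ± 0.15 (SE, n = 5 per group; limma adjusted p = 0.0101). Of 25 regulators of the MAPK cascade 7 rose and 18 did not pass, with 10 higher when adjusted over the list alone (median 0.31, camera adjusted p = 0.0329; adjusted p = 0.783 with an estimated correlation). Map3k5, the stress kinase ASK1, rose by 0.55 ± 0.12 (adjusted p = 0.0195, and 0.0535 without AngII 2). Of 16 heat shock genes 3 rose and 13 did not pass, with 7 higher and 1 lower when adjusted over the list alone (median 0.24, camera adjusted p = 0.0439; adjusted p = 0.783 with an estimated correlation). The chaperones Hspa8 (0.54 ± 0.11, adjusted p = 0.0162) and Hsp90aa1 (0.69 ± 0.15, adjusted p = 0.0164) were among them. Without Control 3 and Control 5 no member of these 3 lists was called by limma (camera adjusted p = 0.0114, 0.188 and 0.107 in the order given). The MAPK call ended without Control 3 (0.0729), Control 5 (0.0658) or AngII 5 (0.0576). The heat shock call ended without Control 1 (0.0714), Control 3 (0.0543), Control 4 (0.069), Control 5 (0.0658), AngII 3 (0.0763), AngII 4 (0.0556), AngII 5 (0.0576) or AngII+QDG 1 (0.0505).

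Nuclear-encoded oxidative phosphorylation genes, mitochondrial genome transcripts and cytosolic ribosomal protein genes were lower as groups relative to all genes. Before the median of all genes (0.20) was subtracted, the list medians were −0.16, −0.18 and −0.16 log2 units in the order given. Of 46 nuclear-encoded oxidative phosphorylation genes 5 fell, 1 rose and 40 did not pass, with the same counts adjusted over the list alone (median −0.36 relative to all genes, camera adjusted p = 1.16e-08; adjusted p = 0.782 with an estimated correlation), and Cox5b was the one that was still called without Control 3 and Control 5. The cytochrome oxidase subunit Cox7a1 fell by 0.59 log2 units (adjusted p = 0.0219), a call that ended without AngII 2 (0.0554) or AngII 4 (0.0552). With the short-transcript balance as a covariate Cox7a1 went to −0.040 ± 0.13 and Cox5b to −0.25 ± 0.11, while Cox4i1 went from −0.48 to −0.43 ± 0.21 (SE). Of 32 cytosolic ribosomal protein genes limma called 0, also when adjusted over the list alone, with a list median of −0.36 relative to all genes (camera adjusted p = 3.76e-08; adjusted p = 0.782 with an estimated correlation). Of 11 mitochondrial genome transcripts 3 fell and 8 did not pass, with 3 lower when adjusted over the list alone (median −0.38, camera adjusted p = 0.00583, and 0.0754 without Control 5; adjusted p = 0.782 with an estimated correlation). mt-Cytb fell by 0.30 log2 units (adjusted p = 0.0222; 0.0561 without AngII 4 and 0.0567 without AngII 5), but changed by 0.0043 with quantile normalization. Under quantile normalization the camera adjusted p was 0.517 for oxidative phosphorylation, 0.139 for ribosomal proteins and 0.979 for mitochondrial transcripts. The transcripts of these 3 lists were short, with list medians of 1232, 1124 and 957 nt for the longest transcript, on the side to which the Control libraries leaned. With the length trend of each library removed, oxidative phosphorylation (camera adjusted p = 0.00131) and ribosomal proteins (0.0026) were still called lower and mitochondrial transcripts were not (0.572), and median scaling also called the first (1.31e-06) and the second (3.65e-06) but not the mitochondrial transcripts (0.208). Other lists of energy metabolism were not called lower. Of 31 genes of the tricarboxylic acid cycle and branched-chain amino acid catabolism 6 rose and 0 fell (median 0.11 relative to all genes, camera adjusted p = 0.341, and 0.00298, higher, with quantile normalization). Of 32 fatty acid oxidation genes 2 rose and 1 fell (camera adjusted p = 0.896, and 0.0131, higher, with quantile normalization), and of 23 glycolysis and glucose uptake genes 3 rose and 0 fell (camera adjusted p = 0.975). In these 3 lists the counts were the same adjusted over the list alone.

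Oxidative stress and NRF2 target genes moved both ways. Of 29 members 1 rose, 3 fell and 25 did not pass, with 1 higher and 4 lower when adjusted over the list alone. The list median was −0.02, its mean 0.01 and its median relative to all genes −0.22, and the camera test called it lower (adjusted p = 0.00583; adjusted p = 0.782 with an estimated correlation; 0.139 with quantile normalization). Hmox1, heme oxygenase 1, rose by 1.18 ± 0.27 (SE, n = 5 per group; limma adjusted p = 0.0202, and 0.0535 without AngII 2). Gpx4, a lipid peroxide reductase, fell by 0.31 log2 units (adjusted p = 0.0288), a call that ended without Control 2 (0.0545), Control 3 (0.0602), AngII 2 (0.0734) or AngII 4 (0.0661). Genes of antigen presentation by MHC class II were lower as a group of 7 (median −0.67 relative to all genes, camera adjusted p = 0.00184; adjusted p = 0.783 with an estimated correlation), although limma called 0 of them, also adjusted over the list alone. H2-Ab1 changed by −0.70 ± 0.30 (adjusted p = 0.125). Complement genes (15 members, median −0.44, camera adjusted p = 0.0329) and erythroid markers (6 members, median −0.54, camera adjusted p = 0.0454) were lower as groups relative to all genes, with 0 members called by limma, also adjusted over the list alone, and an adjusted p = 0.783 with an estimated correlation. Before the median of all genes was subtracted, complement genes had a median of −0.24 and a mean of −0.04. Erythroid markers then had −0.34 and −0.36, and MHC class II genes −0.47 and −0.45. The complement call ended without Control 1 (0.13), Control 3 (0.077), AngII 1 (0.091), AngII 2 (0.0571) or AngII 3 (0.0909), and with quantile normalization (0.0813). The erythroid call ended without Control 2 (0.0602), Control 3 (0.194), Control 5 (0.134), AngII 1 (0.0546), AngII 2 (0.185), AngII 3 (0.0763), AngII 5 (0.0687) or AngII+QDG 1 (0.0509), and with quantile normalization (0.425).

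Of 46 lists tested, camera called 13 between AngII and Control (6 higher, 7 lower), 7 without Control 3 and 8 without Control 5. The directions depended on the setting: quantile normalization called 10 lists (9 higher, 1 lower, 7 of them among the 13), median scaling 10 (6 higher, 4 lower), and fry, which does not compare a list with other genes, 10 that were each higher, 6 of them among the 13. With the length trend removed 8 of the 13 were called, and besides mitochondrial transcripts the calls of MAPK regulators (camera adjusted p = 0.0506), NRF2 targets (0.0644), complement (0.0641) and erythroid markers (0.6) ended; median scaling ended those of complement (0.116) and erythroid markers (0.322). With an estimated correlation 0 were called (limma camera; the unadjusted gene count above applies), and the adjusted p of each of the 13 was then 0.782 or 0.783. Genes lowest in AngII by fold included Kazald1 (−1.26 ± 0.22, limma adjusted p = 0.00863; −1.10 and 0.0619 over transcripts listed in every file) and Fkbp2 (−1.20 ± 0.23, adjusted p = 0.0131). The calls of Kazald1 and Fkbp2 ended without Control 3 and Control 5. Ribosomal pseudogenes such as Rps6-ps3 (−0.66 ± 0.13, adjusted p = 0.0131) share reads with their parent genes and are uncertain. Of the other genes chosen in advance, Tgfb1 (−0.09 ± 0.18, adjusted p = 0.747), Timp1 (0.46 ± 0.32, 0.34), Agtr1a, the AngII receptor gene (0.76 ± 0.55, 0.355), Cdkn1a (0.18 ± 0.30, 0.713) and Atp2a2, the calcium pump gene (0.30 ± 0.13, 0.146, and 0.023 without Control 4), did not pass.

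The second comparison asked how hearts of AngII mice given QDG differ from those of AngII mice without it. Collagens and matrix enzymes had lower values in AngII+QDG hearts as groups, while limma called 0 single genes. Both calls were lost with an estimated correlation (0.485 for collagens and 0.266 for enzymes, camera adjusted p = 0.972 each). Of 100 splits of the same 10 libraries, the real one included, 84 called at least as many lists. The collagen list had a median of −0.33 log2 units relative to all genes (16 members, camera adjusted p = 0.0217), with Col4a1 at −0.55 ± 0.26, Col5a2 at −0.46 ± 0.21 and Col5a3 at −0.46 ± 0.18 (SE, n = 5 per group; limma adjusted p = 0.998, 0.998 and 0.922). The matrix enzyme list had a median of −0.13 (23 members, camera adjusted p = 0.0243), with Timp1, a metalloproteinase inhibitor, at −0.82 ± 0.32 (adjusted p = 0.934) and Loxl2, a collagen-crosslinking oxidase, at −0.71 ± 0.34 (adjusted p = 0.998). Limma called 0 members of either list, also adjusted over the list alone. The collagen call ended without AngII 5 (0.213) or AngII+QDG 2 (0.0867), and the enzyme call without AngII 5 (0.218), AngII+QDG 1 (0.0766) or AngII+QDG 2 (0.0867). Fibroblast markers were not called (12 members, median 0.10 relative to all genes, or 0.08 before this subtraction, mean −0.08, camera adjusted p = 0.92).

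As a score per library, the mean of the list minus the library median, collagens were 0.26 ± 0.35 in Control, 0.69 ± 0.29 in AngII and 0.39 ± 0.20 in AngII+QDG (SD, n = 5 each). The collagen difference was 0.43 for AngII against Control (exact two-sided permutation p = 0.0635, adjusted p = 0.127 over 6 tests) and −0.30 for AngII+QDG against AngII (exact permutation p = 0.103, adjusted p = 0.155). Matrix enzymes scored 0.68 ± 0.06 in Control, 0.98 ± 0.17 in AngII and 0.76 ± 0.12 in AngII+QDG (SD, n = 5 each). That difference was 0.30 for AngII against Control (exact permutation p = 0.00794, adjusted p = 0.0476) and −0.22 for AngII+QDG against AngII (exact permutation p = 0.0397, adjusted p = 0.119).

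**Figure D3:**
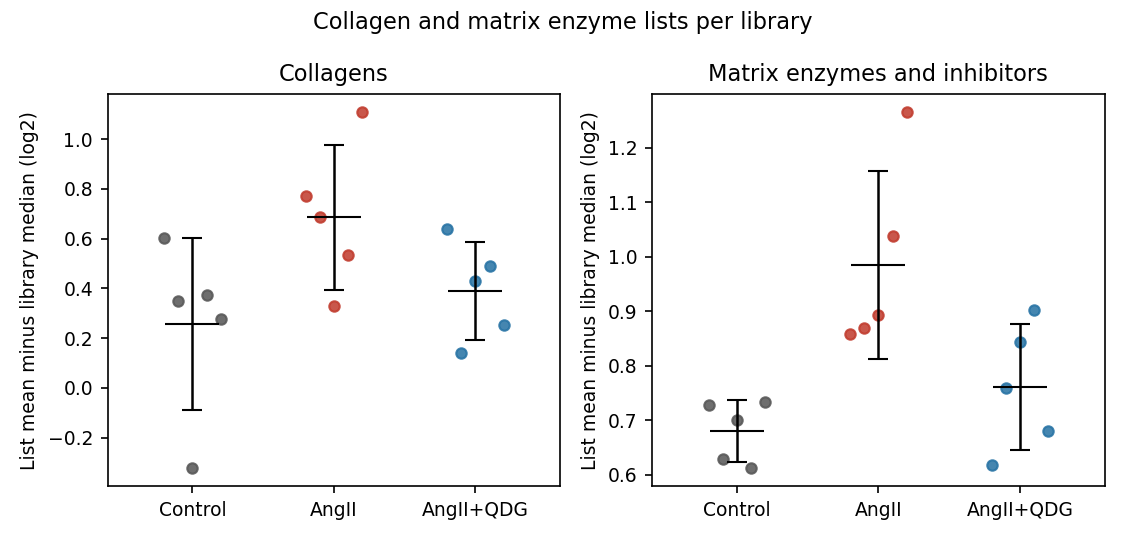
Scores of the collagen list (left) and of the matrix enzyme and inhibitor list (right) in each library, as the list mean minus the library median in log2 units, with group mean ± SD (n = 5) in black. Enzyme scores average 0.98 in AngII, 0.68 in Control and 0.76 in AngII+QDG, and the collagen scores of the 3 groups overlap.

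Between AngII+QDG and AngII limma called 0 of 12258 genes, with 579 at an unadjusted p under 0.05 and a smallest adjusted p of 0.172. The other settings called 0, except those that called 1 gene or 3 transcripts, which are named further on. Gid8, a subunit of a ubiquitin ligase, was at 1.99 ± 1.10 against 8.95 ± 4.22 FPKM (SD, n = 5 each; −1.69 ± 0.30 log2 units SE, limma adjusted p = 0.172). Tax1bp1, an autophagy adaptor, was at 20.4 ± 2.70 against 13 ± 1.85 FPKM (0.61 ± 0.13, adjusted p = 0.512). Wdr35 (−1.32 ± 0.21), Cacnb3 (−1.18 ± 0.21) and Slc39a11 (−0.83 ± 0.15) also stood at adjusted p = 0.172, and Cacnb3 and Slc39a11 were listed at 0 in 4 AngII+QDG libraries. A call appeared for Cacnb3 without AngII 4 (adjusted p = 0.00908), for Slc39a11 without AngII+QDG 3 (0.0119), for Wdr35 without AngII+QDG 4 (0.0197), and without AngII 2 for Arhgap5 (0.022), a gene chosen after its values were seen. Other genes near the top lay partly in transcripts listed in the files of only 1 set: over transcripts in every file Wdr35 went from −1.32 to −0.56, Sdccag8 from −1.09 to 0.02, Mfsd4a from 0.81 to 0.09 and Cacnb3 from −1.18 to −0.68. Immediate early genes held 3 members lower when adjusted over the list alone (camera adjusted p = 0.179): Klf4 at −1.25 ± 0.39, Dusp1, a MAPK phosphatase, at −0.89 ± 0.25 and Klf2 at −0.71 ± 0.18 (adjusted p over all genes 0.742, 0.685 and 0.665). Of the 14 genes chosen in advance limma called 0, with Nppa at −0.49 ± 0.31, Nppb at −0.25 ± 0.73, Acta1 at −0.78 ± 0.41, Postn at −0.46 ± 0.39, Col1a1 at −0.43 ± 0.30 and Ccn2 at 0.44 ± 0.35 (adjusted p = 0.998 each). Of 46 lists camera called the 2 matrix lists and, without AngII 5, 0 lists. Without AngII+QDG 2 it called 1 list, which was not a matrix list. Without AngII+QDG 1 it called 2, of which 1 was a matrix list. It called 4 without Control 2, AngII 1 or AngII+QDG 4, 5 without AngII 2 and 6 without AngII+QDG 5. These each held the 2 matrix lists.

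The third comparison set AngII+QDG hearts against Control. Ccn2 rose by 2.54 ± 0.35 log2 units (SE; limma adjusted p = 0.00153), to 99.2 ± 35.9 FPKM from 15.1 ± 2.18 (SD, n = 5 each). Timp3 (1.14 ± 0.15, adjusted p = 0.00116), Adamts1 (1.40 ± 0.20, 0.00167), Ankrd1 (1.22 ± 0.22, 0.00437) and Tnfrsf12a (1.02 ± 0.19, 0.00478) rose too. Rises by over 2 log2 units included Tjp1 (2.17 ± 0.18, 5.25e-05), Rhobtb1 (2.92 ± 0.57, 0.00555), the translation factor Eif5 (2.57 ± 0.49, 0.00519) and the transcription factor Tcf4 (2.17 ± 0.35, 0.00243). Klf9, a transcription factor, rose by 3.48 ± 0.80 (0.01), a call that ended without Control 3 and Control 5. Insr, the insulin receptor gene, fell from 3.52 ± 0.248 to 0.149 ± 0.131 FPKM (−1.98 ± 0.38, limma adjusted p = 0.00537). In AngII libraries Insr stood at 5.82 FPKM in AngII 1 and at 0.0240 to 0.294 in the others. Gid8 fell by 1.40 log2 units (0.00805, not called without Control 3 and Control 5). Gene sums leave out assembled transcripts without a gene name, so they may not hold all reads of a gene. Hba-a2, an alpha-globin gene that shares reads with its paralog, fell by 2.78 (0.0268), a call that ended without Control 5 (0.0656), AngII+QDG 1 (0.0726), AngII+QDG 2 (0.0561) or AngII+QDG 3 (0.0504).

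Ribosomal protein genes and nuclear-encoded oxidative phosphorylation genes were lower as groups in AngII+QDG than in Control. Of 32 ribosomal protein genes 6 fell, 0 rose and 26 did not pass, with 9 lower when adjusted over the list alone (median −0.45 relative to all genes, camera adjusted p = 9.04e-10, and 0.168 with quantile normalization; adjusted p = 0.883 with an estimated correlation). Rpl6 fell by 0.37 log2 units (limma adjusted p = 0.0313), a call that ended without Control 3 (0.0715), Control 5 (0.0617), AngII+QDG 1 (0.0844), AngII+QDG 4 (0.0511) or AngII+QDG 5 (0.058). Of 46 oxidative phosphorylation genes 10 fell, 2 rose and 34 did not pass, the same counts adjusted over the list alone (median −0.34, camera adjusted p = 9.12e-08; adjusted p = 0.883 with an estimated correlation), but with quantile normalization the list's own median log2 change was 0.04 and the camera adjusted p was 0.863. Cox5b fell by 0.49 (adjusted p = 0.00416) and Atp5d, a subunit of ATP synthase, by 0.62 (0.00921). Of 29 NRF2 targets 8 fell, 2 rose and 19 did not pass, with 8 lower and 3 higher adjusted over the list alone (median −0.21, camera adjusted p = 0.00251, and 0.185 with quantile normalization; adjusted p = 0.883 with an estimated correlation), Gpx4 by 0.40 (0.00592) and the metallothionein Mt1 by 0.68 (0.0122; not called without Control 3 and Control 5). MHC class II genes had a median of −0.64 (7 members, 0 called by limma, also adjusted over the list alone; camera adjusted p = 0.00768, 0.0995 without Control 1, 0.118 with quantile normalization; adjusted p = 0.883 with an estimated correlation). Before the median of all genes was subtracted, the list medians were −0.17 for oxidative phosphorylation, −0.04 for NRF2 targets and −0.46 for MHC class II. Of 31 genes of the tricarboxylic acid cycle and branched-chain amino acid catabolism 7 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.286), and of 32 fatty acid oxidation genes 5 rose and 0 fell, with 4 higher adjusted over the list alone (camera adjusted p = 0.67). Of the collagens 2 rose and 14 did not pass (camera adjusted p = 0.543), and of the matrix enzymes 4 rose and 19 did not pass (camera adjusted p = 0.452). The Control libraries of this comparison are those with the short-transcript balance and zeros given above. Without Control 3 and Control 5 limma called 3 oxidative phosphorylation genes lower and 1 higher, and 4 NRF2 targets lower and 1 higher. Camera then still called 3 of the 4 lists, with an adjusted p of 0.00388 for oxidative phosphorylation and 0.0326 for NRF2 targets, but not MHC class II (0.103).

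Limma called 2377 genes between AngII+QDG and Control (1971 higher and 406 lower; 4162 at an unadjusted p under 0.05). The median log2 change of all genes was 0.18 (0.088 without Control 5, 0.053 without Control 3 and Control 5), and with quantile normalization 983 genes were called higher and 999 lower, with median scaling 790 higher and 1622 lower. The count was 1202 (970 higher, 232 lower) without Control 3 and Control 5, and 0 in limma (1103 at an unadjusted p under 0.05) with the short-transcript balance as a covariate. With it the median size of the change of the 2377 genes went from 0.62 to 0.27 log2 units and the median standard error from 0.15 to 0.22, and the change of 210 of them did not shrink. Ccn2 went from 2.54 ± 0.35 to 2.57 ± 0.61, Timp3 from 1.14 ± 0.15 to 1.05 ± 0.25, Tnfrsf12a from 1.02 ± 0.19 to 1.21 ± 0.33, Insr from −1.98 ± 0.38 to −2.19 ± 0.68 and Atp5d from −0.62 ± 0.14 to −0.043 ± 0.14. Of 39 called genes followed across settings 28 were still called without Control 3 and Control 5. Leaving out single libraries gave 1452 (without AngII+QDG 1) to 3022 (without Control 4) genes, and of these AngII+QDG 1 moved the count by over 1.5 times. Of 46 lists camera called 4, each lower, and 7 without Control 4. With quantile normalization it called 3 others, each higher: the natriuretic and fetal programme (camera adjusted p = 0.0168), fatty acid oxidation (0.00847) and the tricarboxylic acid cycle with branched-chain amino acid catabolism (0.000593). With median scaling it called 4 (1 higher, 3 lower), without MHC class II (0.0841). With the length trend removed it called 3 (1 higher, 2 lower), without MHC class II (0.207) and NRF2 targets (0.0661). Of the 14 genes chosen in advance limma called Ccn2, and Myh7 (0.95 ± 0.37, adjusted p = 0.0856, 0.0492 without Control 1), Postn (0.96 ± 0.39, 0.0954, 0.0406 without Control 1) and Atp2a2 (0.35 ± 0.13, 0.0777, 0.00974 without Control 4) did not pass, nor did Nppa (0.20 ± 0.31, 0.685).

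The last comparison asked whether genes that differed between AngII and Control went the opposite way in AngII+QDG against AngII. Of the 1639 genes called, 743 (45.3%) had the opposite sign, against 54.3% of all genes. By direction, 43.3% of the genes higher in AngII were lower in AngII+QDG, and 61.3% of those lower in AngII were higher. Both contrasts use the AngII libraries, which by itself gives opposite signs. In 100 simulations with an AngII effect and no QDG effect the share averaged 64.0% (range 25.1 to 94.3%). In 20 splits of the AngII libraries between the contrasts the share of the 1639 genes averaged 46.8% (27.3 to 70.8%). These genes were called with all AngII libraries, so the splits do not undo that choice. Among genes called anew in each split (5 to 1289 genes) the share ran from 10.5 to 71.4%. Across genes, which are not independent replicates, the correlation of the 2 sets of log2 fold changes was −0.18 and their covariance −0.019. Simulated groups with no effect gave a correlation of −0.49 and a covariance of −0.038, and those with the AngII effect alone −0.27 and −0.035. Split libraries gave 0.073 and 0.011. The covariance exceeded that of the 2 kinds of simulation by 0.019 and 0.015 on average, but lay inside their ranges (−0.066 to −0.0053 and −0.091 to 0.0064). Genes called in both contrasts numbered 0 in limma, as no gene was called in the second contrast, where 579 had an unadjusted p under 0.05.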

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

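The explanations weighed for the transcripts near 0 were tested after the result was seen, except the move to assembled transcripts, whose test was set before. Single libraries far from the rest of their group were looked for in 363 groups of 5 libraries, and 28 were found. Chance gives about 1 in 20, or 18.2. They numbered 7 in Control, 9 in AngII and 12 in AngII+QDG, with 5 in AngII 5, 4 in AngII+QDG 1, and 3 each in Control 5 and AngII+QDG 3. The value given for each is the gap to the nearest library divided by the group's range.

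Among Control libraries, Slmap was high in Control 2 (gap 0.747; 6.62 FPKM against 0.0404 to 0.722), Carns1 in Control 2 (1; 0.0114 FPKM, with the others listed at 0), Btnl9 in Control 4 (0.962; 6.57 FPKM, the others up to 0.0800) and Cd74 in Control 1 (0.748; 181 FPKM against 64.0 to 83.4). Control 5 was low for Agtr1a (0.932; 0.176 FPKM against 9.58 to 11.4), Kcnj12 (0.766; listed at 0, others 1.83 to 2.89) and Cd163 (0.782; 1.48 against 3.09 to 3.70).

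Among AngII libraries, AngII 5 was low for Carns1 (0.786; 1.90 FPKM against 5.67 to 7.37), mt-Co2 (0.761; 26915 against 31116 to 32569), the mitochondrial share of FPKM (0.912; 37.6% against 43.1 to 43.6%) and the retained intron share (0.772; 2.35% against 2.71 to 2.81%), and high for Loxl2 (0.770; 6.70 FPKM against 2.80 to 3.47). AngII 1 was low for Tax1bp1 (0.926; 9.71 FPKM against 13.7 to 14.1) and high for Insr (0.877; 5.82 against 0.0240 to 0.294). AngII 4 was high for Hspd1 (0.725; 93.3 FPKM against 20.3 to 31.1) and low for Ubl7 (0.753; 15.4 against 28.5 to 34.8).

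Among AngII+QDG libraries, AngII+QDG 1 was low for Ccn2 (0.715; 39.9 FPKM against 94.9 to 134), Timp1 (0.773; 1.37 against 2.26 to 2.58) and Rpl6 (0.723; 182 against 213 to 227), and high for Insr (0.873; 0.382 against 0.0727 to 0.108). AngII+QDG 2 was low for Col8a1 (0.731; 1.86 FPKM against 3.88 to 4.94) and Klf9 (0.836; 1.07 against 18 to 28.3). AngII+QDG 3 was high for Flnc (0.758; 43.9 FPKM against 32.9 to 35.3) and Slc39a11 (1; 0.640, others listed at 0), and low for Inmt (0.789; 4.91 against 10.9 to 13.4). AngII+QDG 4 was high for Maff (0.806; 10.4 FPKM against 6.33 to 6.99) and Lox (0.784; 1.60 against 0.330 to 0.538), and AngII+QDG 5 was high for Cacnb3 (1; 0.125 FPKM, others listed at 0).

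Assembled transcripts without a gene name, outside the gene comparisons, also differed. Of 6902 tested, limma called 149 between AngII and Control (135 higher, 14 lower) and 359 between AngII+QDG and Control (309 higher, 50 lower).

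Several of the large AngII folds, such as those of Bms1 and Carns1, came from transcripts near 0 in Control libraries. Among 5475 transcripts of 5 to 30 FPKM in AngII+QDG, values under 0.1 FPKM made up 6.14% in Control and 2.39% in AngII, 2.57 times as many. Control 5 was highest at 12.3%. The other Control libraries ranged from 2.92 to 6.47%, and AngII libraries from 2.08 to 2.78%. Lower detection in Control libraries may account for part of the pattern. The transcripts were chosen by their AngII+QDG level, however, so a rise under AngII shared by AngII+QDG would give the same excess. Fragments averaged 69.1 times 1000000 in Control and 68.0 times 1000000 in AngII, which argues against total depth. Mitochondrial genes and their copies took 46.0% of FPKM in Control and 42.3% in AngII on average, and depth without them was not tested. FPKM may also have moved to other transcripts of the same gene: for 59 of 136 such transcripts (43.4%) the gene's sum rose by under 50% of their log2 change. Assembled transcripts near 0 in AngII (7 of 6902) were 11.9% as frequent as named ones near 0 in Control (184 of 21573). Those near 0 in Control numbered 84 of 6902, so assembled transcripts too were near 0 more often in Control than in AngII. These counts argue against a whole move to assembled transcripts for most of the 184. A move of part of the FPKM to them is not covered by these counts and stays open. An effect of AngII on these genes was not tested apart from these.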

How the results depend on the processing

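Tests chosen after the result was seen are those with shared transcripts, transcripts, mitochondrial genes left out, length, the covariate, Control 3 and Control 5 left out, no library at 0, voom, and the scaling of lists. The 1639 genes of AngII against Control became 818 with quantile normalization, 1074 with median scaling, 317 with 2 groups only, 218 with a fold threshold of 1, 712 as transcripts, 342 with the length trend removed, 97 without Control 3 and Control 5, and 0 with the covariate (limma; 749 at an unadjusted p under 0.05). Leaving out 1 library gave 316 (AngII 2) to 2488 (Control 4). The 2377 genes of AngII+QDG against Control became 1448 with 2 groups, 362 with the fold threshold, 1307 with length removed, 1202 without Control 3 and Control 5 and 0 with the covariate (limma; 1103 unadjusted), and 1452 (without AngII+QDG 1) to 3022 (without Control 4). The covariate lowered the median size of the changes and raised their median standard error; for the other settings the cause was not tested. AngII+QDG against AngII, 0 in limma with 579 unadjusted, gave 1 gene with pseudocounts of 0.1 and 0.01 (Cacnb3, adjusted p = 0.0154 and 0.0159), with sample weights and the covariate (Wdr35, 0.0434 and 0.0419) and with voom (Thsd7a, 5.10 log2 units, 0.0105, chosen after its values were seen), 3 as transcripts (assembled, without gene names), and 0 to 1 without 1 library. Voom on the recovered fragments called 1775, 1 and 2262 genes, of which 1428 and 2002 of the first and last were shared with the calls on FPKM. A negative-binomial count test on these fragments was not run.

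The 13 lists of AngII against Control became 0 with an estimated correlation (limma camera; 3858 genes at an unadjusted p under 0.05), 8 with length removed, 7 without Control 3 and Control 5, 10 with quantile normalization (9 higher, 1 lower), 10 with median scaling (6 higher, 4 lower), 10 with fry (each higher), and 7 (without Control 3) to 13 without 1 library. The 2 lists of AngII+QDG against AngII became 0 with an estimated correlation and 0 with fry (limma; 579 genes unadjusted), 5 without genes that have a library at 0, and 0 (without AngII 5) to 6 (without AngII+QDG 5). The 4 lists of AngII+QDG against Control became 0 with an estimated correlation and with fry (limma; 4162 genes unadjusted), 3 others with quantile normalization (each higher, where the 4 were lower), and 3 (without Control 1) to 7 (without Control 4). The share of opposite changes, 45.3%, was 54.3% over all genes. Apart from fry, which does not compare a list with other genes, and the estimated correlation, the cause was not tested.

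Of 2455 values of the 77 genes followed in AngII against Control, 2040 kept direction and side of the threshold, 15 (of 9 genes, 8 of them with the covariate) changed sign without a call in either setting, 383 lost the call, 12 gained it and 5 called ones changed sign. The 5 were Col4a1 (−0.0033), Mapk8 (−0.024) and mt-Nd3 (0.030) with the covariate, and mt-Cytb (0.0043) and mt-Co2 (0.012) with quantile normalization. Of 1143 values of 36 genes in AngII+QDG against AngII, 1123 kept both, 13 (of 6 genes) changed sign without a call and 7 gained a call. Of 1719 values of 54 genes in AngII+QDG against Control, 1598 kept both, 31 (of 10 genes, 10 with the covariate) changed sign without a call, 83 lost the call, 5 gained it and 2 called ones changed sign with the covariate: Rpl6 (0.11) and Cox7a1 (0.0018).

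With the replicate number as a block, AngII against Control gave 516 genes and 11 lists, AngII+QDG against AngII 0 genes (limma, 541 unadjusted) and 2 lists, AngII+QDG against Control 1857 genes and 4 lists, and the share of opposite changes was 45.9%. Same-numbered libraries correlated at −0.0961 to 0.0877, and 3 of 30 comparisons were highest with the library's own number, so no common deviation was seen. Whether a number marks a shared litter, batch or day cannot be told from this, and the labels do not say. Depth limits values of 5 to 30 FPKM little in AngII+QDG, where 4553 named transcripts at this level held a median of 1251 fragments (the 5475 above include assembled transcripts). This does not cover Control libraries, nor genes that lay below 5 FPKM in a group, such as Tjp1, Insr and Gid8.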

Other observations

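Tests of the length balance, the mitochondrial share, Control 5, AngII 5, fibroblasts and simulated list scores were chosen after the result was seen, as were the settings without Control 3 and Control 5 and with the covariate. Some lists that camera did not call in AngII against Control held members that limma called. Of 27 PI3K-AKT-mTOR and FoxO genes 7 rose and 1 fell, with 13 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.109). Of 26 p53 and apoptosis genes 6 rose (8 adjusted over the list alone; camera adjusted p = 0.419), among them Sesn1, a stress-responsive inhibitor of growth signalling (0.61 log2 units, limma adjusted p = 0.0195, and 0.0537 without AngII 2). Of 20 calcium handling genes 5 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.899). Ryr2, the calcium release channel, rose by 1.00 (adjusted p = 0.0222; 0.0603 without AngII 2 and 0.0516 without AngII 4), and Camk2d, a calcium-dependent kinase, by 1.45 (0.0231; 0.0622 without AngII 2 and 0.0569 without AngII 5). None of these 3 genes was called without Control 3 and Control 5. With the short-transcript balance as a covariate Ryr2 went to 0.026 ± 0.20, Camk2d to 0.80 ± 0.54 and Sesn1 to 0.53 ± 0.22 (SE).

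In AngII+QDG against Control, Lmod2, an actin filament nucleator of muscle, rose from 134 ± 27.1 to 324 ± 75.1 FPKM (SD, n = 5 each; 1.26 ± 0.18 SE, limma adjusted p = 0.00167). Pdk4, a kinase that limits pyruvate oxidation, rose from 19.9 ± 11 to 49.4 ± 17.7 FPKM (1.35 ± 0.29, adjusted p = 0.00824), and Flt1, a VEGF receptor of endothelium, from 10.9 ± 2.37 to 21.6 ± 4.09 (0.93 ± 0.16, 0.00317). Sesn1 rose by 1.03 ± 0.14 (0.00139) and Cd163, a scavenger receptor of macrophages, by 0.87 ± 0.19 (0.00747). With the short-transcript balance as a covariate, which ended each of these calls, Pdk4 went to 0.27 ± 0.37, Flt1 to 0.55 ± 0.24 and Cd163 to 0.34 ± 0.27 (SE). Lmod2 then stood at 1.10 ± 0.32 and Sesn1 at 0.94 ± 0.23. Of 14 endothelial markers 3 rose and 2 fell, with 4 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.973), and of 15 macrophage markers 2 rose, also adjusted over the list alone (median −0.32 relative to all genes, or −0.15 before this subtraction, mean 0.0078, camera adjusted p = 0.282). Whether these genes differ from their change under AngII alone is the comparison of AngII+QDG with AngII, in which limma called 0 genes (579 at an unadjusted p under 0.05; voom called 1).

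Most genes called between AngII and Control were higher in AngII. With mitochondrial genes left out and the other genes rescaled to the same total, 90.0% of calls were higher. This cannot decide whether a larger mitochondrial share in Control plays a part. The rescaling also evens out total FPKM, which averaged 792404 in Control and 705754 in AngII. Control 5 alone is argued against as the whole cause, as 88.2% of calls were higher without it. The median change of all genes then went from 0.20 to 0.11, however, and the higher calls from 1458 to 700. The lean of Control libraries to short transcripts may account for the shift: the slope of the library median on this balance within groups gives 118% of the group difference (58.6 to 177%), and 91.3% without Control 3 and Control 5 (11.8 to 171%). Balance and median come from the same FPKM values, so lower values of long transcripts move both, and part of the slope arises by construction. The slope therefore cannot decide whether the lean is the cause. With the balance as a covariate every call ended: the median change of the 1639 genes went from 0.60 to 0.25 log2 units and its standard error from 0.16 to 0.21, but 115 changes did not shrink, such as those of Tnfrsf12a (1.48 ± 0.19 to 1.66 ± 0.31, adjusted p = 0.262) and Ccn2 (2.10 ± 0.35 to 2.13 ± 0.58, 0.66), while Tjp1 went from 2.16 ± 0.18 to 1.81 ± 0.27 (0.0977). Because the balance differs between the groups, an effect of AngII on it stays open as well.

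Collagens and matrix enzymes were higher in AngII than Control and had lower values in AngII+QDG than AngII. With the AngII libraries shared by both contrasts split between them, both lists had opposite signs in 20 of 20 splits, but the lists were picked from 46 for their calls in these libraries, and such a pick favours this outcome. Among 100000 simulated sets of scores of the 2 lists, with an AngII effect and no QDG effect, 29954 had the pattern by sign. Of these 15.1% gave at least 18 such splits. A pattern as strong as the observed one arose in 7 sets, and 100% of these 7 gave at least 18 such splits. The count of splits thus adds little once the pattern is that strong. The simulations do not repeat the pick from 46 lists, so the shared libraries stay open. Whether these libraries, AngII 5 alone or fewer fibroblasts could account for the pattern cannot be told apart from an effect of QDG on the matrix: without AngII 5 the collagen median was −0.20 relative to all genes (SE 0.13; camera adjusted p = 0.213, and 0.218 for the enzymes), and fibroblast markers that are not collagens changed by 0.24 more than collagens (SE 0.13), too close to their spread to decide.

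Other splits of the same 10 libraries, 100 per comparison with the real one included, were counted for each result. Of these splits only the real one called as many genes for AngII against Control (1639 genes, highest other 532). The same held for AngII+QDG against Control (2377, highest other 12). This argues against a random grouping of the libraries as the source of these counts. The splits cannot tell treatment from the groups' difference in short-transcript balance. With that balance as a covariate limma called 0 genes in each (749 and 1103 at an unadjusted p under 0.05). Chance cannot be excluded for the lists of any comparison. For AngII against Control 8 splits called at least the real 13 lists (median of the other splits 6, highest 19). For AngII+QDG against AngII 84 splits called at least the real 2 (median of the others 3, highest 15). For AngII+QDG against Control 71 splits called at least the real 4 (median of the others 6, highest 14). For the genes of AngII+QDG against AngII, where limma called 0 (579 unadjusted; highest other split 3), each of the 100 splits calls at least as many, so the count of splits tests nothing.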
